A study of Danio rerio with 6 samples.

How the data were processed

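The series holds single-cell RNA sequencing of cells sorted from transgenic zebrafish embryos, in 6 libraries of 3 groups with 2 libraries each: the drl sort (draculin:mCherry positive, gata1:GFP negative) at 30 hpf and at 52 hpf, and the runx1:mCherry sort at 52 hpf, whose gate used no GFP. Per the labels, libraries were made with the Chromium Single Cell 3' kit version 3.1 and sequenced on an Illumina HiSeq. The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger 4.0.0 per the file headers. The submitters' processing notes also name Seurat 4 and the builds GRCz11 and danRer11, and no coordinates are used here. The deposited barcodes were already filtered, with a lowest total of about 500 UMIs. Gene symbols and identifiers were taken as the files pair them, and the 1170 of 25109 features that share a symbol carry their identifier after the symbol. The features GFP and mCherry were left out of the sums tested.

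Libraries 1 and 2 held 81446088 and 18973142 UMIs in 3595 and 874 barcodes (drl, 30 hpf), 170398290 and 186506145 in 10230 and 10549 (drl, 52 hpf), and 152755010 and 129427341 in 10491 and 6975 (runx1, 52 hpf). Barcodes with at least 300 genes and at most 10% of UMIs from the 13 mitochondrially encoded genes were kept, after calling doublets with scrublet through scanpy 1.11.5 in each library alone. Of 42714 barcodes 3387 had fewer genes, 144 more mitochondrial UMIs, and 7 were called doublets. These groups overlap: 3440 barcodes were left out and 39274 kept. An automatic threshold that calls 7 of 42714 barcodes has not worked, so an alternative removing the highest doublet scores at 0.8% per 1000 barcodes was added. Intervals and floors cover counting error only; the upper limit for a count of 0 was taken as 3 counts, in each library for shares of cells, and the counting intervals are at 95%.

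Cells of all libraries were clustered together without batch integration, with Leiden (leidenalg 0.10.2) at resolution 1 on 30 principal components of the log-normalised counts of 2000 variable genes and 15 neighbours, seed 0. The globin-poor cells, those of clusters with a median globin share under 50%, were clustered again in the same way, a step added after the files were seen; clusters of the first level are called L1c and those of the second L2c. Each globin-poor cluster took the marker list, fixed beforehand, with the highest mean log2 fold over the median cluster, with a prior of 10 CPM, when at least 3 markers were raised over 1.5-fold and found in at least 10% of cells. Globin-rich clusters were scored against the globin-poor ones and named erythroid-like unless at least 3 markers of another type led them. A cluster with more markers of another class than of its own among its top 10 genes was left unnamed, as was a cluster with few UMIs for its libraries and no marker of its own among them. This rule was revised with class names and cells in view, through 4 versions, before any test was run, so that a class being named across settings is partly a product of the rule. By the rule that used leading genes over the median cluster, no HSPC-like cells were named at resolution 2 or with doublet calls ignored, and by scores over the mean of the other clusters the class was cluster L2c1 alone, with 221 cells, and erythroid-like cells numbered 28694 in place of 35670, with 8147 cells unnamed in all. Of the kept cells 925 lay in clusters left without a name, 3.73% of cells at 30 hpf, 0.538% in the drl sort at 52 hpf and 4.00% in the runx1 sort.

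UMI counts were summed per library over all kept cells and over each class, and libraries with fewer than 20 cells of a class were left out of its fit. Sums were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in a fit without intercept of all libraries with enough cells, so that the groups share an estimate of the spread; Benjamini-Hochberg adjusted p under 0.05 was called. The comparisons were the drl sort at 52 against 30 hpf and the runx1 against the drl sort at 52 hpf. Class shares were tested with edgeR on cells per class over the 11 named classes. Gene lists fixed beforehand were tested with camera of limma 3.58.1 at a correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a comparison. Each list's count of called genes is given over all genes tested and adjusted over the list alone. The line effect was compared between HSPC-like and erythroid-like cells with limma.

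CPM values are scaled by TMM, except those of the reporters, of the haem genes in parts of the HSPC-like class, and where said, which are of the summed cells' own total. Named genes were those of the gates (drl, gata1a, runx1) and the HSPC genes myb, gata2b and itga2b; per comparison, the 8 (whole sort) or 6 (class) genes with the largest fold each way among those called, with a mean of at least 20 CPM, libraries of the groups not overlapping and a symbol that is no placeholder; and up to 4 members of each list with the smallest adjusted p, or with the highest CPM where none passed. Genes read off clusters and the hepatic-led cluster were chosen after their values were seen.

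The scripts were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. Of these, 1 and 11 were recovered in the whole sort between stages, 0 and 2 between lines, 9 and 54 in erythroid-like cells between stages, 8 and 76 between lines, 52 and 87 in HSPC-like cells, 0 and 14 in macrophage-like cells, and 18 and 91 in lymphoid-like cells. Unchanged genes called numbered 0, 0, 2, 6, 8, 1 and 5 in that order. The neutrophil-like fit had no such test. In the test of the line effect between classes 134 of 200 changed genes were recovered, with 6 other calls. Its counts had a preset spread, the same for every gene, and changed genes were only raised. The 6 other calls therefore do not gauge false calls in the real data.

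Alternatives were DESeq2 1.42.0, its size factors in edgeR, no gene filter, only the groups compared, a block of the replicate number, each library left out, at least 600 genes and at most 5% mitochondrial UMIs, doublet calls ignored, resolution 2, and sums thinned to the smallest. Added after seeing the data were library totals as sizes in place of TMM, ranked doublet scores, first-level clusters, globin genes left out, the erythroid-like class without the hepatic-led cluster L1c10, another naming score, shares outside the erythroid-like class, crossed replicate numbers, lymphoid-like cells, and neutrophil-like cells with at least 10 cells per library. With 2 libraries per group no other splits of the samples were counted. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, umap-learn 0.5.12, matplotlib 3.10.9 and the R package data.table, version 1.17.8.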

Results

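Single-cell transcriptomes were collected from blood-forming cells sorted from transgenic zebrafish embryos. The first sort took cells carrying an mCherry reporter of draculin (drl, a zinc-finger gene of early mesoderm and blood) and no GFP reporter of gata1, the gene of the main erythroid transcription factor. It was made at 30 and at 52 hours post fertilisation (hpf). The other sort took cells carrying an mCherry reporter of runx1, a transcription factor needed for blood stem cells to emerge, at 52 hpf. Each of the 3 groups had 2 libraries. The 6 libraries held between 874 and 10549 barcodes and between 18973142 and 186506145 UMIs, the tags that count single transcripts. After filtering, 39274 of 42714 barcodes were kept, with a median of 10832 to 23701 UMIs per cell. Nothing in the labels says that the libraries of a group came from separate clutches, so p-values measure only the spread between these libraries. That spread can be technical. The design implies 2 comparisons: the drl sort at 52 against 30 hpf, and the runx1 sort against the drl sort at 52 hpf. The drl libraries at 52 hpf enter both on opposite sides, so opposite changes in the comparisons are not independent. Levels are means ± SD over n = 2 libraries in CPM, counts scaled to a common library total by TMM unless said otherwise. Fold changes are log2 values ± SE with adjusted p-values from edgeR's quasi-likelihood test.

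In CPM of a library's own total, mCherry lay at 1974 and 707 in the libraries of the drl sort at 30 hpf, at 117 and 136 in those at 52 hpf, and at 10.9 and 24.1 in the runx1 sort. GFP, which the drl gate left out, lay at 0.123 and 14.1 at 30 hpf and at 24.8 and 17.6 at 52 hpf. In the runx1 sort 0 GFP UMIs were found among the 151218033 and 128962634 UMIs of its libraries, which allows up to 0.0198 and 0.0233 CPM.

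**Figure D1:**
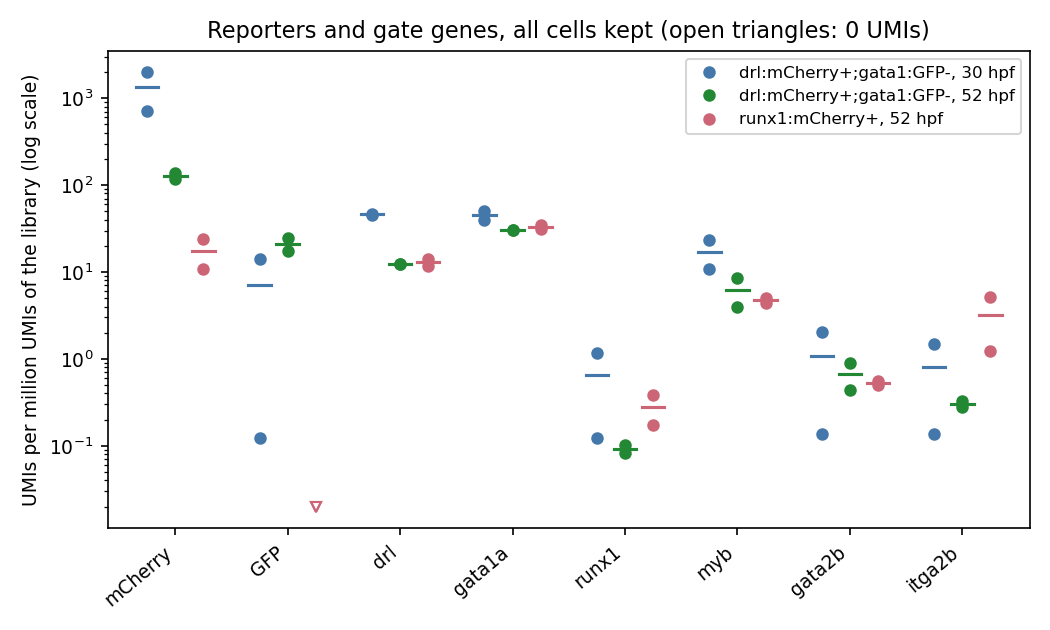
Reporter and gate genes in CPM of each library's own total (log axis), over all cells kept. Each point is a library, each bar the mean of a group with no library at 0, and the open triangle stands for both runx1 libraries at 0 GFP UMIs; the points of mCherry lie between 707 and 1974 in the drl sort at 30 hpf and at or under 24.1 in the runx1 sort.

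In the drl sort, the makeup of the sorted cells changed between 30 and 52 hpf. Endothelial-like cells fell from 15.5 ± 9.88% of the cells at 30 hpf to 0.0546 ± 0.0132% at 52 hpf (log2 fold -8.09 ± 1.48, adjusted p = 0.000691, n = 2 libraries each). Macrophage-like cells fell from 5.17 ± 3.18% to 0.332 ± 0.149% (-3.96 ± 1.29, adjusted p = 0.0174). Neutrophil-like cells fell from 2.93 ± 1.73% to 0.245 ± 0.122% (-3.59 ± 1.21, adjusted p = 0.0174). Lymphoid-like cells numbered 0 of 4283 at 30 hpf. With 3 counts as the limit in each library that allows up to 0.0866% in library 1 and 0.366% in library 2, a mean of 0.226%. They made up 0.300 ± 0.0884% at 52 hpf, at least 1.33-fold over that mean (adjusted p = 0.0174) but under the limit of library 2. With ranked doublet scores 1 and 8 lymphoid-like cells were named in the libraries at 30 hpf and the log2 fold was 0.97 (adjusted p = 0.522), so the count of 0 and the bound do not hold there. Neural-like, epidermis-like and mesenchyme-like cells also fell (-4.76, -5.52 and -5.46, adjusted p = 0.0174, 0.0174 and 0.0216).

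Erythroid-like cells made up 54.0 ± 29.6% at 30 hpf and 96.4 ± 1.66% at 52 hpf (0.84 ± 1.07, adjusted p = 0.447), although the gate excluded cells bright for gata1:GFP. HSPC-like cells, those with markers of haematopoietic stem and progenitor cells, numbered 13 at 30 hpf and 240 at 52 hpf, or 0.653 ± 0.801% and 1.31 ± 0.598% (1.12 ± 1.29, adjusted p = 0.439). Counted among the cells outside the erythroid-like class, a denominator chosen after the shares were seen, HSPC-like cells rose from 1.08 ± 1.04% to 36.6 ± 0.274% (5.10 ± 1.06, adjusted p = 0.00508). Of all cells their share was also called with another naming score, chosen after seeing the data (4.0 ± 1.41, adjusted p = 0.0193). With the denominator outside the erythroid-like class endothelial-like cells fell from 33.6 ± 0.142% to 1.62 ± 0.381% (-4.39 ± 0.87, adjusted p = 0.00508). Thrombocyte-like cells, 0 of 1418 at 30 hpf, reached 2.56 ± 1.71% on that scale, at least 5.74-fold over the mean limit of the libraries (0.446%; adjusted p = 0.00681). Of all cells they made up 0 of 4283 at 30 hpf and 0.0773 ± 0.0188% at 52 hpf (adjusted p = 0.0847; 0.039 at resolution 2). That share lies under the limit of either library at 30 hpf, so the count of 0 sets no lower bound on the fold, and the call depends on the clustering. Lymphoid-like cells reached 8.77 ± 1.60% of the cells outside the erythroid-like class, at least 19.7-fold higher (adjusted p = 0.00388), a bound that rests on the same count of 0. The falls of the other classes were not called with that denominator. The gates and the number of erythroid cells that passed them set all of these shares together with the embryo. Without library 1 of the drl sort at 52 hpf, edgeR called 0 of the 11 classes (2 at unadjusted p under 0.05), and without its library 2 it called 3. With ranked doublet scores it called endothelial-like cells alone (adjusted p = 0.0025). In that setting 53 and 98 lymphoid-like cells were named in the drl libraries at 52 hpf, in place of 21 and 34. HSPC-like cells of these libraries numbered 48 and 82, in place of 78 and 162, so the sizes of both classes depend on the setting. Without library 2 at 30 hpf the log2 fold of the share of mesenchyme-like cells turned to 3.85 (adjusted p = 0.439). Those of neural-like (-0.01, adjusted p = 0.993) and epidermis-like cells (-3.28, adjusted p = 0.111) were not called without it, while HSPC-like cells were (3.89 ± 0.87, adjusted p = 0.0356). Without library 1 at 30 hpf the fold of HSPC-like cells was 0.10 (adjusted p = 0.895), and erythroid-like (1.54 ± 0.35, adjusted p = 0.0204) and muscle-like cells (-2.94 ± 0.51, adjusted p = 0.012) were called. Macrophage-like (-3.13 ± 1.03, adjusted p = 0.0587) and lymphoid-like cells (adjusted p = 0.0975) were not called without that library.

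**Figure D2:**
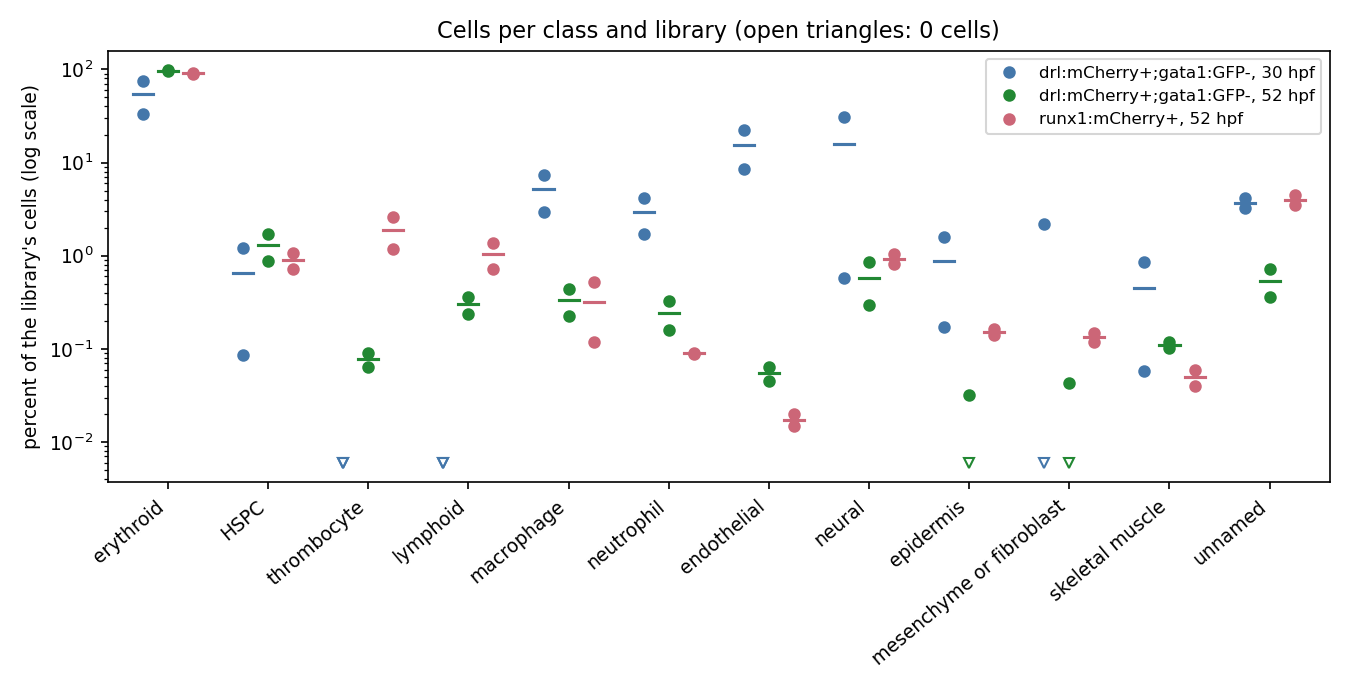
Percent of each library's kept cells in each class (log axis). Each point is a library, each bar the mean of a group with no library at 0, and open triangles mark libraries with 0 cells; endothelial-like cells lie above 8% in both 30 hpf libraries and under 0.1% in all 4 at 52 hpf.

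Over all sorted cells of the drl sort, 692 genes rose and 442 fell of 15348 tested between 30 and 52 hpf. These directions are relative to the bulk of the genes, which TMM takes as unchanged. With library totals as sizes, an alternative chosen after seeing the data, folds moved by a median of -2.15 over the whole sort and -1.60 in erythroid-like cells, and 148 genes were called higher and 9053 lower over the whole sort. The cytochrome oxidase subunit gene cox4i1l rose from 0.403 ± 0.189 to 53.5 ± 10.3 CPM (7.08 ± 0.56, adjusted p = 0.0181). The mitochondrial transcription factor gene mterf3 rose from 1.55 ± 1.00 to 134.8 ± 25.3 CPM (6.43 ± 0.63, adjusted p = 0.0181). The solute carrier gene slc6a22.2 (5.58 ± 0.87), the RNA-binding protein gene rbm38 (4.56 ± 0.50) and the cyclin gene ccni (4.42 ± 0.40) rose as well (adjusted p = 0.0279, 0.0188 and 0.0181). Among the genes that fell were the cystatin gene cst14b.2 (-7.40 ± 0.61, adjusted p = 0.0181) and the keratin gene krt18a.1 (-3.17 ± 0.39, adjusted p = 0.0212). The tropomyosin gene tpm4a (-3.04 ± 0.53, adjusted p = 0.0336) and marcksl1a, which encodes an actin-regulating protein (-2.76 ± 0.38, adjusted p = 0.0233), fell too.

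Of the gene lists fixed beforehand, S-phase genes fell over the whole sort, 20 of 29 (28 adjusted over the list alone). Among them were the replication helicase gene mcm5 (-2.53 ± 0.32) and the DNA ligase gene lig1 (-2.46 ± 0.36; camera adjusted p = 3.93e-11, adjusted p = 0.768 with an estimated correlation). Of 22 endothelial markers 9 fell (22 adjusted over the list alone). These included the endothelial cadherin gene cdh5 (-3.48 ± 0.57) and the receptor gene tie1 (-3.35 ± 0.55; camera adjusted p = 2.47e-09, adjusted p = 0.768 with an estimated correlation). Of 10 embryonic globins 2 rose (9 adjusted over the list alone). They were hbae5, by 4.38 ± 0.58, and hbbe2, by 4.21 ± 0.62 (camera adjusted p = 3.43e-06, adjusted p = 0.768 with an estimated correlation). Of 12 thrombocyte markers 4 rose (5 rose and 2 fell adjusted over the list alone), but with library totals as sizes 1 rose and 3 fell. Those that rose included the platelet glycoprotein gene gp9 (3.20 ± 0.51) and the thrombopoietin receptor gene mpl (4.96 ± 0.79; camera adjusted p = 0.0439, adjusted p = 0.768 with an estimated correlation). The gate gene drl itself lay at 18.5 ± 8.38 CPM at 30 hpf and 20.9 ± 3.87 CPM at 52 hpf (0.17 ± 0.41, adjusted p = 0.783). The other gate gene, gata1a, lay at 17.5 ± 4.64 CPM at 30 hpf and 50.6 ± 9.73 CPM at 52 hpf (1.53 ± 0.41, adjusted p = 0.0724). The scaling turned both directions: in CPM of a library's own total drl lay at 46.8 and 44.9 in the libraries at 30 hpf and at 12.4 in both at 52 hpf (-1.89, adjusted p = 0.00648). On that scale gata1a lay at 39.9 and 50.8 at 30 hpf and at 30.3 and 30.0 at 52 hpf (-0.59, adjusted p = 0.0839). The libraries at 30 hpf stood apart from each other, with a median globin share per cell of 56.8% in library 1 and 0.184% in library 2. In that order 74.9% and 33.0% of their cells were erythroid-like.

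The count over the whole sort was 0 in edgeR without library 1 or without library 2 of the drl sort at 52 hpf (1902 and 2666 genes at unadjusted p under 0.05). It was 4597 and 2759 without library 1 or 2 at 30 hpf. It was also 0 with only these 4 libraries in the fit (4154 at unadjusted p under 0.05), while DESeq2 called 3311 genes, 1657 higher and 1654 lower.

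Within erythroid-like cells, genes of DNA replication and cell division fell between 30 and 52 hpf in the drl sort and most embryonic globins rose relative to the bulk of the genes. Of 29 S-phase genes 28 fell (28 adjusted over the list alone). Among them were the replication factors gins2 (-5.02 ± 0.43, from 17.6 ± 3.97 to 0.542 ± 0.0688 CPM, adjusted p = 0.000357) and mcm10 (-4.89 ± 0.31, adjusted p = 0.000334). Of 30 genes of G2 and mitosis 27 fell and 1 rose (the same counts adjusted over the list alone). Those that fell included the proliferation marker mki67 (-3.08 ± 0.27) and the spindle checkpoint kinase gene ttk (-2.66 ± 0.26). Of 10 embryonic globin genes 9 rose and 1 fell (the same counts adjusted over the list alone), with hbae3 higher by 2.51 ± 0.23 and hbbe2 by 3.33 ± 0.31. With library totals as sizes 29 genes of each of the cell cycle lists fell, and of the globins 4 rose and 1 fell. Camera's adjusted p was 2.63e-13, 7.94e-10 and 0.00873 for these 3 lists, and each had an adjusted p = 0.763 with an estimated correlation.

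The genes of haem synthesis went both ways in erythroid-like cells under TMM, while with library totals as sizes 0 rose and 10 fell. The gene alas2, the erythroid enzyme of its first step, rose by 2.07 ± 0.23 (from 353 ± 30.1 to 1485 ± 14.5 CPM), and by 0.52 with library totals as sizes (adjusted p = 0.15). The genes hmbsa and cpox, enzymes of later steps, fell by 2.57 ± 0.29 and 3.19 ± 0.32. Of 14 measured 3 rose and 7 fell (the same counts adjusted over the list alone; camera adjusted p = 0.315). The progenitor transcription factor gene myb fell (-4.60 ± 0.69, from 6.38 ± 4.82 to 0.268 ± 0.0745 CPM, adjusted p = 0.00171), as did drl (-0.98 ± 0.29, adjusted p = 0.0275). The gene gata1a differed by 0.50 ± 0.38 (adjusted p = 0.313), and by -0.99 with library totals as sizes (adjusted p = 0.0409). Large rises were those of mterf3 (6.35 ± 0.47), cox4i1l (6.18 ± 0.74) and slc6a22.2 (4.87 ± 0.43). Large falls were those of the thioredoxin gene txn (-5.94 ± 0.64), the nucleolar gene npm1a (-5.52 ± 0.90; -2.66 and adjusted p = 0.058 with the other naming score) and rpa3, part of the single-strand DNA-binding complex (-4.91 ± 0.43). Of 13 mitochondrially encoded genes 7 rose (7 adjusted over the list alone; camera adjusted p = 0.0472, adjusted p = 0.763 with an estimated correlation), and 2 fell and 0 rose with library totals as sizes. In all 2489 genes rose and 2581 fell of 11446 tested, against 367 and 6948 with library totals as sizes.

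Different clusters held the erythroid-like cells of the stages: L1c6, led by genes such as hmgb2a and pcna, held 98.3% of them at 30 hpf and 1.46% at 52 hpf. The count fell from 5070 to 2673 without library 1 and to 2683 without library 2 at 52 hpf, and to 3012 with the sums thinned to the depth of the smallest library.

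**Figure D3:**
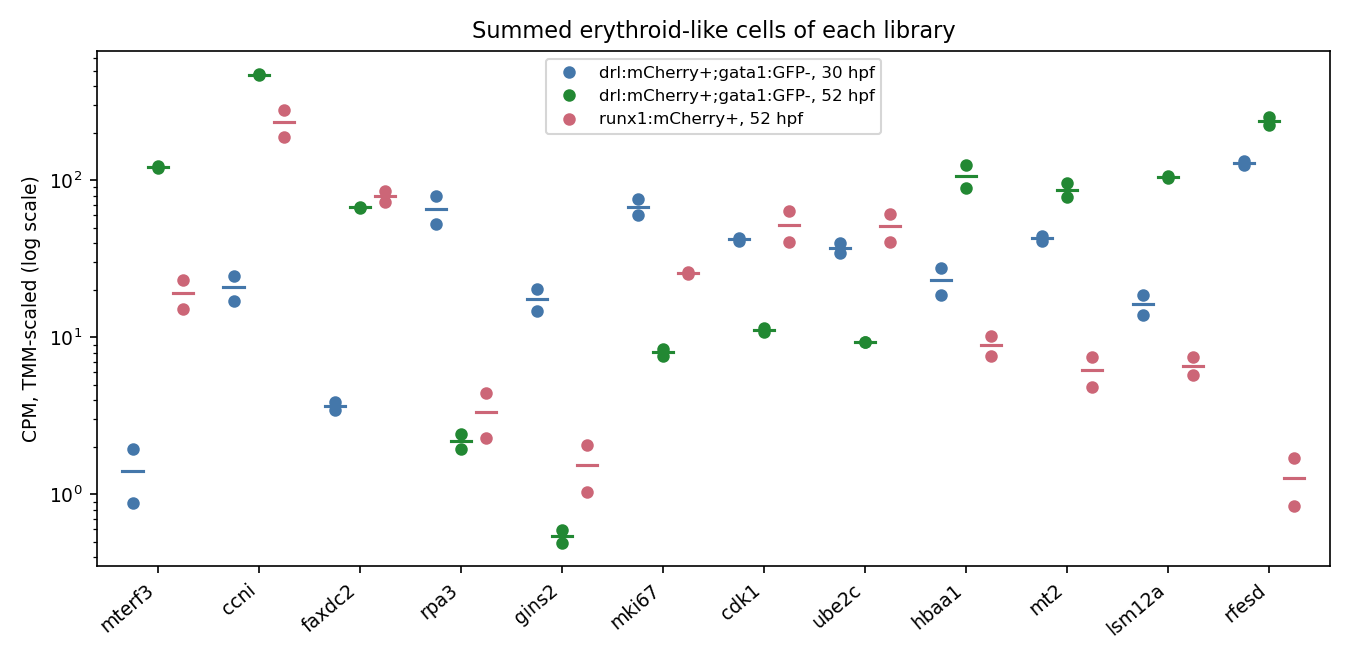
Expression of 12 genes in the summed erythroid-like cells of each library, in TMM-scaled CPM (log axis). Each point is a library and each bar the mean of a group; in the drl sort mterf3 lies at 1.42 ± 0.756 CPM at 30 hpf and 122 ± 2.05 CPM at 52 hpf, and rfesd lies at 239 ± 21.3 CPM in the drl sort and 1.28 ± 0.618 CPM in the runx1 sort at 52 hpf.

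In macrophage-like cells of the drl sort, 7 genes rose and 3 fell of 4518 between 30 and 52 hpf. The lysozyme gene lyz, abundant in neutrophils, fell from 843 ± 489 to 5.23 ± 7.40 CPM (-6.88 ± 0.83, adjusted p = 0.0311). The cystatin gene cst14b.2, a leading gene of neutrophil-like cells here, had 1808 UMIs at 30 hpf and 3 at 52 hpf (adjusted p = 0.0236), a ratio of 101 with a 95% counting interval of 34.4 to 489. It also fell over the whole sort and in neutrophil-like cells, so its fall is not read as a change of macrophage-like cells. Of 10 neutrophil markers 1 fell (4 adjusted over the list alone; camera adjusted p = 0.0334, adjusted p = 0.649 with an estimated correlation). The globin gene hbae5 rose from 5.41 ± 4.74 to 145 ± 7.51 CPM (4.39 ± 0.59, adjusted p = 0.0414). Over the whole sort it rose by 4.38 ± 0.58, so its rise is not read as a change of these cells. Globins held 3.1 and 0.0780% of the UMIs of macrophage-like cells in the libraries at 30 hpf and 3.48 and 8.15% at 52 hpf. Of 10 embryonic globins 1 rose (1 adjusted over the list alone; camera adjusted p = 0.00029, adjusted p = 0.649 with an estimated correlation). Of the class, 85.0% at 30 hpf lay in cluster L2c0 and 65.6% at 52 hpf in L2c16. The leading genes of L2c16 lgals3bpb, ccl34b.1 and ctsl.1 were among the genes that rose and are not read as changes here. The count was 0 in edgeR without library 2 at 52 hpf (214 genes at unadjusted p under 0.05), while DESeq2 called 67 with all libraries. It was 26 without library 1 at 52 hpf, and 353 and 694 without library 1 or 2 at 30 hpf. HSPC-like and endothelial-like cells were not compared between the stages, since a library held fewer than 20 of them, and neutrophil-like cells were compared only with a minimum of 10 cells per library.

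At 52 hpf the runx1 sort held more thrombocyte-like cells than the drl sort, 1.89 ± 1.01% against 0.0773 ± 0.0188% (4.58 ± 1.3, adjusted p = 0.0365, higher in both libraries). Lymphoid-like cells made up 1.04 ± 0.459% against 0.300 ± 0.0884% (1.79 ± 1.14, adjusted p = 0.461). HSPC-like cells made up 0.898 ± 0.242% against 1.31 ± 0.598% (-0.54 ± 1.22, adjusted p = 0.811). Erythroid-like cells made up 90.5 ± 2.86% against 96.4 ± 1.66% (-0.09 ± 1.06, adjusted p = 0.957). With the other naming score they made up 50.3 ± 7.55% against 94.3 ± 0.591% (-0.91 ± 1.03, adjusted p = 0.542), and 44.6 ± 5.50% of the cells of the runx1 sort went without a name. Among the cells outside the erythroid-like class, HSPC-like cells made up 9.49 ± 0.312% against 36.6 ± 0.274% (-1.95 ± 0.90, adjusted p = 0.13) and thrombocyte-like cells 19.1 ± 4.83% against 2.56 ± 1.71% (2.94 ± 0.95, adjusted p = 0.0897). With that denominator edgeR called 0 classes (4 at unadjusted p under 0.05). The call of thrombocyte-like cells was also lost with doublet calls ignored, at resolution 2 and with ranked doublet scores (adjusted p = 0.135, 0.0983 and 0.119). The runx1 gate used mCherry alone and the drl gate also left out GFP, so the gate and the reporter differ together with the line. No class was called by edgeR without any single library of the 4 (0 classes at unadjusted p under 0.05 without library 1 of the drl sort or library 2 of the runx1 sort, and 1 without either of the others).

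Over all sorted cells, 18 genes were higher and 28 lower in the runx1 sort than in the drl sort at 52 hpf, of 15348 tested, and 1 and 6 with library totals as sizes. A histone H4 gene (hist1h4l_ENSDARG00000115281) lay at 56.1 ± 9.20 against 4.99 ± 0.442 CPM (3.49 ± 0.37, adjusted p = 0.0445; adjusted p = 0.149 with library totals as sizes), and near-identical copies of it can share counts. Of 30 genes of G2 and mitosis 0 passed over all genes and 22 were higher adjusted over the list alone. The mitotic kinase gene cdk1 lay at 67.7 ± 30.3 against 17.3 ± 0.615 CPM (1.97 ± 0.54, adjusted p = 0.222; camera adjusted p = 1.97e-16, adjusted p = 0.905 with an estimated correlation). Of 14 neutrophil markers 0 passed and 3 were lower adjusted over the list alone (camera adjusted p = 0.000142, adjusted p = 0.905 with an estimated correlation). Of 6 hepatic and yolk markers 0 passed and 5 were higher adjusted over the list alone (camera adjusted p = 0.0372, adjusted p = 0.905 with an estimated correlation). Of these apoa2 lay at 174 ± 244 against 0.620 ± 0.0939 CPM (8.12 ± 2.54, adjusted p = 0.28). Library 2 of the runx1 sort held 910 of the 1060 cells of the hepatic-led erythroid-like cluster L1c10. Levels of drl, myb and gata1a differed by -0.03 ± 0.41, -0.42 ± 0.65 and 0.09 ± 0.40 (adjusted p = 0.99, 0.866 and 0.963). Leaving out any of the 4 libraries in turn, 0 genes were called by edgeR (800 and 939 at unadjusted p under 0.05 without library 1 or 2 of the drl sort, 1372 and 1045 without library 1 or 2 of the runx1 sort). With all libraries DESeq2 called 704 and edgeR on these 4 libraries alone 881.

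Within erythroid-like cells at 52 hpf, mitotic genes were higher in the runx1 sort. Most larval and adult globin genes were lower there, while globins together held a larger share of the UMIs. Of 30 genes of G2 and mitosis 27 rose (28 adjusted over the list alone). These included the spindle gene nusap1 (2.30 ± 0.29, 23.9 ± 4.38 against 4.84 ± 0.215 CPM, adjusted p = 0.00399), ttk (1.90 ± 0.25, adjusted p = 0.00424) and cdk1 (2.23 ± 0.29, adjusted p = 0.00431). Of 5 larval and adult globins 3 fell and 1 rose (the same counts adjusted over the list alone; camera adjusted p = 0.264). The gene hbaa1 lay at 8.89 ± 1.86 against 107 ± 25.6 CPM (-3.59 ± 0.35, adjusted p = 0.00158). Of 10 embryonic globins 4 fell (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.197), among them hbbe1.1 (-1.42 ± 0.27) and hbae5 (-1.71 ± 0.35). The haem enzyme gene alas2 fell by 1.32 ± 0.22 and the erythroid gene hemgn by 1.19 ± 0.23 (adjusted p = 0.00916 and 0.0145; hemgn 0.0516 with library totals as sizes). Near-identical globin copies can share counts. All globins together held 87.6 and 88.0% of the UMIs of erythroid-like cells in the runx1 libraries and 84.0 and 84.1% in the drl libraries. The falls are thus of single globin genes and not of globin as a whole.

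Of 29 immediate early and heat shock genes, the set that tissue dissociation raises, 9 fell (10 adjusted over the list alone). Among them were jund (-3.78 ± 0.69), fosb (-3.0 ± 0.50) and ier2a (-2.25 ± 0.33; adjusted p = 0.0124, 0.00909 and 0.00591). Of 83 ribosomal protein genes 8 fell (3 adjusted over the list alone), among them rpl23a (-1.3 ± 0.23) and rps18 (-1.28 ± 0.27), and 1 with library totals as sizes. Camera's adjusted p was 6.39e-16 for G2 and mitosis, 0.000129 for the immediate early genes and 5.72e-08 for the ribosomal proteins, and each had an adjusted p = 0.912 with an estimated correlation. Single genes set the lines further apart. The gene rfesd, an iron-sulphur domain gene, lay at 1.28 ± 0.618 against 239 ± 21.3 CPM (-7.54 ± 0.44, adjusted p = 0.000271). The gene lsm12a lay at 6.60 ± 1.24 against 105 ± 1.95 CPM (-3.99 ± 0.30) and the metallothionein gene mt2 at 6.16 ± 1.87 against 87.0 ± 12.1 CPM (-3.82 ± 0.32). Neither drl (0.01 ± 0.29, adjusted p = 0.982) nor gata1a (-0.05 ± 0.37, adjusted p = 0.95) was called.

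In all 749 genes rose and 770 fell of 11446 (781 and 537 with library totals as sizes, which moved folds by a median of 0.13), with different clusters holding the class. Cluster L1c7, led by hmgb2a, tuba8l and cdk1, held 13.9% of the cells in the runx1 sort and 1.73% in the drl sort, and L1c4, led by mt2 and fosab, 0.413% and 19.2%. The genes cdk1 and mt2 are thus among those that define clusters, as are rfesd and lsm12a, which lead cluster L1c0. The count was 394 and 419 without library 1 or 2 of the drl sort and 495 and 538 without library 1 or 2 of the runx1 sort, 550 with thinned sums, and 2798 with these 4 libraries alone.

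HSPC-like cells of the runx1 sort, as clustered at resolution 1, expressed more of the haem synthesis and erythroid genes than those of the drl sort at 52 hpf, while the progenitor genes myb and gata2b were not called. With the class as clustered at resolution 2 the medians of both lists turned, from 1.00 to -0.29 for haem synthesis and from 1.01 to -0.56 for erythroid markers, and edgeR called 0 of 5 and 0 of 10 genes measured (1 and 4 at unadjusted p under 0.05). Of 11 haem synthesis genes 6 rose (7 adjusted over the list alone). Among them were fech, the last enzyme of the pathway (2.78 ± 0.43, 34.3 ± 17.3 against 4.90 ± 1.31 CPM, adjusted p = 0.0185), urod (2.02 ± 0.23, adjusted p = 0.00942) and hmbsa (1.26 ± 0.15, adjusted p = 0.00986). By untested means alas2, alas1 and uros were lower in the runx1 sort, both among the cells that resolution 2 keeps in the class and among those it leaves out. Of 22 erythroid markers 11 rose and 2 fell (13 and 4 adjusted over the list alone). Those that rose included the transferrin receptor gene tfr1a (2.62 ± 0.40), hemgn (1.74 ± 0.19), gata1a (1.39 ± 0.18, 76.9 ± 2.35 against 29.0 ± 4.12 CPM, adjusted p = 0.0115) and the globin hbbe1.3 (1.58 ± 0.15). The rise of hbbe1.3 was also found in lymphoid-like cells, so it is not read as particular to HSPC-like cells. The globin hbbe1.1 fell by 0.81 ± 0.11. Camera's adjusted p was 0.00575 for both lists, and both had an adjusted p = 0.424 with an estimated correlation. The lists overlap, with tfr1a in both, so they are not separate evidence. Only the drl gate left out gata1:GFP, so a difference made by the gates cannot be told apart from one of the lines. Levels of myb (-0.09 ± 0.15, 299 ± 55.3 against 317 ± 27.3 CPM, adjusted p = 0.729), gata2b (0.04 ± 0.28, adjusted p = 0.943) and drl (0.38 ± 0.12, adjusted p = 0.0982) were not called. Among the HSPC regulators tal1 rose by 1.32 ± 0.20 and lmo2 by 0.71 ± 0.12, while the chemokine receptor gene cxcr4b fell by 1.1 ± 0.16 and fli1a by 1.23 ± 0.21. In this list 3 of 10 rose and 2 fell (3 and 3 adjusted over the list alone). With doublet calls ignored edgeR called 0 of 11 haem synthesis genes (6 at unadjusted p under 0.05) and 1 erythroid marker, which fell, and without drl library 2 it called 1 and 2, while DESeq2 called 4 and 12 with all. At resolution 2 hmbsa, hemgn, drl and tal1 turned to -0.40, -1.22, -0.83 and -0.19 and fli1a to 0.02. Of the HSPC regulators edgeR called 0 there and 0 with doublet calls ignored (1 and 5 at unadjusted p under 0.05), 2 without either drl library, and DESeq2 called 4.

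Glycolysis genes fell in runx1 HSPC-like cells, 6 of 14 (7 adjusted over the list alone), among them pgk1 (-1.12 ± 0.16), pkma (-1.2 ± 0.20) and gapdhs (-0.91 ± 0.19; camera adjusted p = 0.00678, adjusted p = 0.424 with an estimated correlation). At resolution 2 and without drl library 2 edgeR called 0 of them (3 and 6 at unadjusted p under 0.05). Of 11 interferon and NF-kB genes 3 fell (5 adjusted over the list alone). They were irf1b (-3.29 ± 0.42), nfkbiaa (-1.60 ± 0.30) and irf7 (-1.82 ± 0.44; camera adjusted p = 0.00575, adjusted p = 0.424 with an estimated correlation). Of 84 nuclear genes of oxidative phosphorylation 7 rose and 3 fell (18 and 4 adjusted over the list alone), with ndufb3 higher by 0.62 ± 0.12 and uqcr10 lower (-0.68 ± 0.12; camera adjusted p = 0.00716, adjusted p = 0.424 with an estimated correlation). Of these 2 lists edgeR also called 0 genes at resolution 2 (4 and 13 at unadjusted p under 0.05) and 0 without drl library 2 (4 and 7). Of 12 mitochondrially encoded genes 6 fell and 1 rose (9 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.0738, 0.424 with an estimated correlation), with mt-co1 at 558 ± 97.4 against 1318 ± 146 CPM (-1.24 ± 0.14, adjusted p = 0.00942). These genes gave 0.706 and 0.583% of the UMIs of HSPC-like cells in the runx1 libraries and 1.02 and 1.12% in the drl libraries. In lymphoid-like cells they gave 0.7623 and 0.6799% against 1.075 and 1.305%, and in erythroid-like cells 0.1604 and 0.1585% against 0.2276 and 0.2111%. Macrophage-like, neutrophil-like and thrombocyte-like cells were lower in both runx1 libraries as well, while neural-like and endothelial-like cells overlapped. These shares were not tested. The fall is therefore not read as particular to HSPC-like cells. The nuclear receptor gene nr4a3, a leading gene of the HSPC-like cluster L2c6 (-3.21 ± 0.33), the cAMP response gene cremb (-2.82 ± 0.30) and the serine synthesis gene phgdh (-2.56 ± 0.31) fell. The cell cycle regulator rgcc (2.63 ± 0.19) and the chaperone gene dnajb1b (2.04 ± 0.20, 959 ± 64.4 against 231 ± 74.1 CPM) rose. The latter belongs to the list of immediate early and heat shock genes that tissue dissociation raises. It was higher in runx1 lymphoid-like cells too, so its rise is not particular to HSPC-like cells. A copy of the ribonucleotide reductase gene, rrm2_ENSDARG00000078069, had 3 UMIs in the runx1 sort and 1180 in the drl sort, a ratio of 162 with a 95% counting interval of 55.2 to 785 (adjusted p = 0.00218). In the same way rfesd had 1 and 296, a ratio of 122 with an interval of 21.7 to 4823 (adjusted p = 0.00546).

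In all 302 genes rose and 276 fell of 6275 tested in HSPC-like cells. Clustering at resolution 2 left 44.1 ± 2.95% of the class in the drl sort and 63.5 ± 4.52% in the runx1 sort out of it. Over the 11 measured haem synthesis genes the median log2 fold was 0.84 (quartiles 0.16 to 1.32) among those cells and -0.03 (-0.63 to 0.27) among the cells kept, differences of means that were not tested. In that order 8 and 5 of the 11 genes were higher in the runx1 sort. The gene alas2 was lower in both parts (-0.93 and -0.77), as were alas1 (-0.25 and -0.03) and uros (-0.22 and -0.56). At that resolution edgeR called 33 genes, 20 of the 578 among them. Of glycolysis, of the interferon and NF-kB response and of oxidative phosphorylation DESeq2 called 4, 1 and 3 genes with all libraries. In the same order the medians were -0.17, -0.44 and 0.02 at resolution 2 against -0.64, -0.78 and 0.16 in the class as compared. With doublet calls ignored edgeR called 2, 1 and 0 (23 of the last at unadjusted p under 0.05). It called 3, 3 and 1 without drl library 1, 12, 10 and 39 without runx1 library 1, and 7, 6 and 31 without runx1 library 2. Of the mitochondrially encoded genes edgeR called 1 at resolution 2, 1 with doublet calls ignored, 4 and 1 without drl library 1 or 2, and DESeq2 4. The count over all genes in HSPC-like cells was 86 with doublet calls ignored, 263 in DESeq2, and 191, 31, 2000 and 1189 without drl library 1, drl library 2, runx1 library 1 or runx1 library 2. Macrophage-like, neutrophil-like and endothelial-like cells were not compared between the lines, since a library held fewer than 20 of them.

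**Figure D4:**
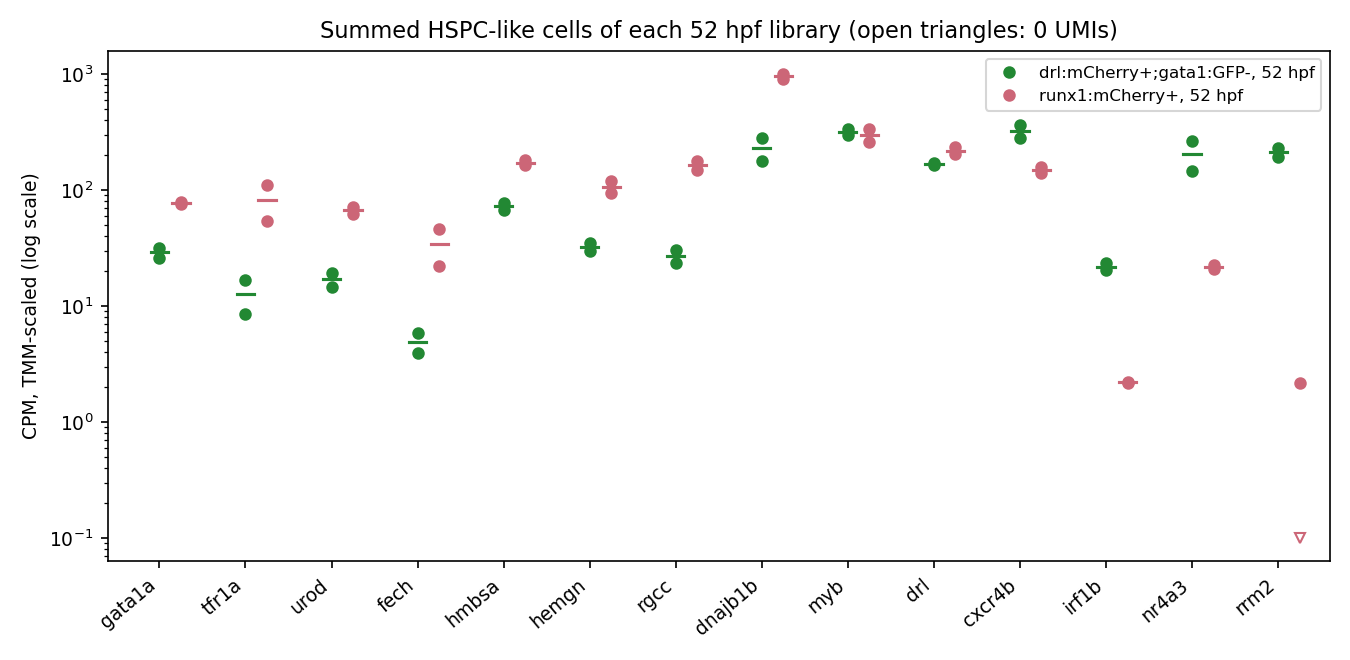
Expression of 14 genes in the summed HSPC-like cells of the 4 libraries at 52 hpf, in TMM-scaled CPM (log axis). Each point is a library, each bar the mean of a group with no library at 0, and the open triangle marks a library with 0 UMIs of rrm2_ENSDARG00000078069; gata1a lies at 76.9 ± 2.35 CPM in the runx1 sort and 29.0 ± 4.12 CPM in the drl sort.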

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

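Of the tests in this part, those of the GFP transcripts, of the second rrm2 copy, and of the haem synthesis genes by globin level, by finer clustering and by shares of UMIs were chosen after the result was seen, and so was the test of the line effect between classes. The bounds for the genes apart between the lines, the summed rrm2 copies, cluster L2c1 and the thinned sums were written before their values were seen, but that quartiles must clear the bound for the haem genes was required afterwards.

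GFP UMIs were found in the drl sort, whose gate left out GFP, in data no comparison of the report uses: 10 and 266 at 30 hpf, of which 8 and 266 lay in neural-like and 0 in erythroid-like cells, and 4169 and 3243 at 52 hpf. Of the latter 4119 and 3140 lay in erythroid-like cells, at a mean of 21.5 CPM, while neural-like cells held 28 and 51 (103 and 58.1 CPM) and thrombocyte-like cells 14 and 2. Of cells with at least 2000 UMIs at 52 hpf, 1183 of 8587 erythroid-like cells (13.8%) of library 1 held a GFP UMI and 0 of 127 HSPC-like, lymphoid-like, macrophage-like and neutrophil-like cells, which allows up to 2.36%, against 1072 of 8901 and 3 of 255 (1.18%) in library 2, at median depths of 19109 and 20316 and of 19627 and 20460 UMIs; a two-sided Fisher's exact p of 1.15e-08 or less in both argues against free RNA spread evenly over the droplets. A test tried before it, at an equal depth of 2000 UMIs, decided nothing, because its 1.70 for library 1 is a lower bound that the 127 cells set, beside a ratio of 6.51 in library 2. Cells below the gate that transcribe the reporter, erythroid-like or not, may hold the transcripts, which cannot be told apart from other sources, since no ungated library is at hand.

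Single genes set the lines far apart in erythroid-like cells, and a haplotype carried by every cell of a line may be a cause, a hypothesis tested in HSPC-like cells. Of 10 genes at least 8-fold apart, globins and rfesd were left out of the test as it was written, and 4 of the others were measured there. These 4 all lay in the erythroid direction, with a median log2 fold of 1.62 (quartiles 0.88 to 2.44), or 2.35 (0.89 to 2.69) with rfesd. Of the 4, mt2 was not called by edgeR in HSPC-like cells (-0.89, adjusted p = 0.524). The fold of lsm12a was -0.84 there against -3.99 in erythroid-like cells, a difference called in the test of the line effect between classes. The median passed the bound of 1.5 written beforehand, but the quartiles span it, so the judgement was made stricter after the value was seen. Haplotype and regulation cannot be told apart for these genes. Free erythroid RNA in the HSPC-like droplets is argued against, since the observed level was 126 times (quartiles 97.2 to 188) the level that it allows. For the rrm2 copies the summed log2 fold was -0.90. The bound set for shared counts was too wide to decide, because the plain loss of 1 of 2 like copies gives about that value and passes it too. The other copy differed by 0.11 ± 0.14, which argues against counts moved from copy to copy.

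Haem synthesis genes were higher in runx1 HSPC-like cells, with biological erythroid priming set against erythroid RNA, the mix of cells and depth. The drl gate left out gata1:GFP and the runx1 gate did not, and gata1a was among the genes that were higher. Gate and line differ together, so no test here can tell an effect of the gate apart from priming. The median of the embryonic globins was -0.086 and decides nothing, because its members went both ways. Scaled to the globin level, RNA of the mean erythroid-like cell gives a median of 0.475% (highest 0.834%) of the level of the 6 haem genes that rose. That argues against RNA of such globin-rich cells as the source. Erythroid cells with little globin are not covered by it. With thinned sums the median over 10 haem genes was 1.27 (quartiles 0.52 to 1.64). Thinning drew from the sums of the same cells, which leaves the expected folds unchanged, so depth per cell was not tested. Median UMIs of HSPC-like cells were 11909 and 18958 in the runx1 libraries and 22295 and 23700 in the drl libraries at 52 hpf. Shares of the class's UMIs allow a log2 fold of at most 0.819 from the cells that finer clustering leaves out and 0.687 from the mix of its clusters. The 6 genes that rose had a median of 1.64 (quartiles 1.07 to 2.47), and 4 of them exceeded 0.819 by their SE. They were picked by their rise in these data, and the median over all 11 measured genes was 1.00. The limits therefore do not settle whether either is the whole cause. Neither the left-out cells nor the mix of clusters can be told apart from a change within cells. The lower quartile was under 0.5 in cluster L2c1 alone (median 0.92, quartiles 0.45 to 1.51) and among those left-out cells (0.843 over 11 genes, 0.16 to 1.32). A haem-rich subset of cells, more abundant or more haem-rich in the runx1 sort, may carry the difference. Because the class and its limits come from these data, this stays a hypothesis.

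The mCherry reporter, which no comparison uses, lay at 1974 and 706.9 CPM at 30 hpf, 116.9 and 135.9 in the drl sort at 52 hpf and 10.9 and 24.12 in the runx1 sort.

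The line effect differed between HSPC-like and erythroid-like cells, tested as an interaction in limma, for 920 of 5832 genes (379 higher and 541 lower in HSPC-like cells). It was run only on the classes as clustered at resolution 1. Among the genes named by the rule, the difference in log2 fold was positive for dnajb1b (3.26), lsm12a (3.14), urod (2.35), tfr1a (2.05), rgcc (1.64) and gata1a (1.40), and negative for tuba8l (-2.43), ube2c_ENSDARG00000114670 (-2.41), cdk1 (-2.01), hmgb2b (-1.93), atp5mc1 (-1.77), tuba1b (-1.73) and knstrn (-1.50).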

How the results depend on the processing

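The alternatives of library totals as sizes, doublet ranking, first-level clusters, the hepatic-led cluster, globins left out, the other naming score, the denominator outside the erythroid-like class, crossed numbers, and the lymphoid-like and neutrophil-like fits were chosen after seeing the data; all others were fixed before the data were examined. Of 2552 values of 157 named gene folds under an alternative, 2212 kept direction and side of the threshold, 272 were no longer called, 26 became called and 42 reversed; of 268 values of 22 class shares the numbers were 209, 40, 9 and 10. Where no cause is given below, the cause was not tested. Simulated data took depth and spread, which were not separated, from all libraries of a fit. The stage and line simulations of a class thus shared them and differed in the group and the genes changed. In these data edgeR recovered 11 of 100 genes changed 4-fold over the whole sort between stages, 2 between lines, and 87 in HSPC-like cells. A library left alone in its group is assumed to vary like the other groups.

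Without single libraries, the calls ranged from 0 to 4597 for the whole sort between stages (1134 with all) and were 0 between lines (46 with all). In erythroid-like cells they ranged from 2673 to 5763 between stages (5070 with all) and from 394 to 538 between lines (1519 with all). In HSPC-like cells it ran from 31 to 2000 (578 with all), in macrophage-like cells from 0 to 694 (10 with all) and in neutrophil-like cells from 3 to 729 (3 with all). Classes called by edgeR fell to 0 and 3 between stages (7 with all) and to 0 between lines (1 with all). At unadjusted p under 0.05 the counts of 0 were 2 between stages and 0 or 1 between lines.

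DESeq2 called 3311 genes over the whole sort between stages (1657 higher and 1654 lower), 704 between lines, 263 in HSPC-like, 67 in macrophage-like and 48 in neutrophil-like cells. With only the libraries of the groups compared, which changes the degrees of freedom, edgeR called 0 genes between stages over the whole sort (4154 at unadjusted p under 0.05), 881 between lines, 2798 in erythroid-like cells between lines, 1 in macrophage-like cells, and 3 classes between stages. With no gene filter it called 155 genes over the whole sort between lines, 2362 in erythroid-like cells, 1218 in HSPC-like, 172 in macrophage-like and 174 in neutrophil-like cells. With stricter cells it called 27 genes in neutrophil-like cells, and with DESeq2's size factors 6. With library totals as sizes in place of TMM it called 9201 genes over the whole sort between stages (148 higher and 9053 lower) and 7 between lines. With sums thinned to the smallest, so at lower depth, it called 2, 3012, 550, 343 and 5 in the whole sort between lines, erythroid-like cells between stages and between lines, HSPC-like and macrophage-like cells. With doublet calls ignored, 86 genes were called in HSPC-like and 6 in macrophage-like cells and 0 classes between lines (1 at unadjusted p under 0.05). That setting adds back 7 barcodes, 0 in both drl libraries at 52 hpf and 1 in library 2 of the runx1 sort, and clusters anew. HSPC-like cells went from 73 to 89 in runx1 library 1 and from 162 to 150 in drl library 2. The fall in HSPC-like calls thus goes with moved class borders rather than with doublets. Resolution 2 gave 33 genes in HSPC-like cells and 0 classes between lines (2 at unadjusted p under 0.05). With ranked doublets 1 class was called between stages and 0 between lines (1 at unadjusted p under 0.05), with first-level clusters 3 and 2, and outside the erythroid-like class 4 and 0 (4 at unadjusted p under 0.05).

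Camera called 15, 11, 6, 3, 5 and 11 lists in the whole sort between stages, whole sort between lines, erythroid-like cells between stages and between lines, HSPC-like and macrophage-like cells. With an estimated correlation it called 0 in each (2, 0, 0, 0, 0 and 0 at unadjusted p under 0.05). Fry called 2, 0, 9, 0, 0 and 1.

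The replicate numbers are not said to mark a shared batch, and with 2 pairs per comparison they were not taken to pair the samples: same-numbered deviations correlated at 0.276 and 0.204 over the whole sort, -0.0406 and 0.00954 in erythroid-like, 0.0687 in HSPC-like, -0.152 in macrophage-like, -0.0712 in lymphoid-like and -0.108 in neutrophil-like cells. With the number as a block edgeR called 1795 genes over the whole sort between stages, 0 between lines (2250 at unadjusted p under 0.05), 278 in HSPC-like cells, 0 in macrophage-like cells (350 at unadjusted p under 0.05), 0 in neutrophil-like cells (268) and 0 classes between lines (3 at unadjusted p under 0.05). With crossed numbers as the block 51 genes were called in macrophage-like and 23 in neutrophil-like cells.

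Reversed folds were mostly of genes not called, and ranges are over single libraries left out. With library totals as sizes drl came to -1.89, itga2b to -1.34, gata2b to -0.646, myb to -1.44 and gata1a to -0.591 over the whole sort between stages, drl to 0.0588 there between lines, and gata1a to -0.992 and 0.084 in erythroid-like cells between stages and between lines; the median shift of all genes by that scaling gives the cause between stages. Over the whole sort between stages drl ranged from -0.243 to 0.776, runx1 from -1.04 to 1.23 and myb from -0.284 to 1.77. Between lines drl ranged from -0.234 to 0.119, gata2b from -0.746 to 0.0213 and gata1a from -0.318 to 0.362. There drl came to 0.039 with the groups compared alone, 0.0178 with stricter cells and 0.0658 with thinned sums. In erythroid-like cells between stages itga2b ranged from -2.94 to 1.33 and gata1a from -0.00269 to 1.2. Between lines drl ranged from -0.0896 to 0.161 and gata1a from -0.194 to 0.121. With ranked doublets drl came to -0.0244, and gata1a came to 0.024 with the groups compared alone, 0.0376 with stricter cells, 0.0751 with thinned sums, 0.0169 with globins left out and 0.0292 with the other naming score. There itga2b came to 1.38 at resolution 2 and 1.81 with the other naming score. In HSPC-like cells resolution 2 turned drl to -0.831, hmbsa to -0.399, hemgn to -1.22, tal1 to -0.186 and fli1a to 0.0205. There gata2b ranged from -0.368 to 0.444 and came to -0.012 with no gene filter, and myb ranged from -0.278 to 0.101.

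Of the class shares between stages, HSPC-like cells turned to -0.111 at resolution 2. Mesenchyme-like cells ranged from -8.97 to 3.85, the latter without library 2 at 30 hpf. Muscle-like cells ranged from -2.94 to 0.906 and came to 0.0929 with stricter cells and 2.17 outside the erythroid-like class. Between lines HSPC-like cells ranged from -0.944 to 0.0240, the latter without drl library 2. Macrophage-like cells ranged from -1.46 to 0.644 and came to 0.0814 with ranked doublets, and neural-like cells came to -0.616 outside the erythroid-like class. Not made for lack of cells were macrophage-like cells between stages with stricter cells, at resolution 2, with ranked doublets and with the other naming score. Lymphoid-like cells with doublet calls ignored and at resolution 2 were not made either.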

Other observations

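The comparisons of lymphoid-like and neutrophil-like cells were chosen after the sizes of the classes were seen, and no hypothesis is offered for them. Lymphoid-like cells of the runx1 sort differed from those of the drl sort at 52 hpf in 22 of 3843 genes, 13 higher and 9 lower. The chaperone gene dnajb1b lay at 1667 ± 109 against 134 ± 80.2 CPM (log2 fold 3.64 ± 0.37, edgeR adjusted p = 0.00763, n = 2 libraries each). The transcription factor genes spi1b, a regulator of myeloid cells (3.54 ± 0.46, adjusted p = 0.0291), id2a (2.78 ± 0.26, adjusted p = 0.00763) and tcf15 (2.06 ± 0.20, adjusted p = 0.00763) were higher, as was the embryonic globin hbbe1.3 (1.77 ± 0.18, adjusted p = 0.00763). The calcium-binding protein gene s100a10b lay at 5.69 ± 5.42 against 133 ± 8.12 CPM (-4.30 ± 0.44, adjusted p = 0.00763). The fatty acid-binding protein gene fabp3 (-2.08 ± 0.19, adjusted p = 0.00763) and ifi45 (-2.0 ± 0.29, adjusted p = 0.0358) were lower. The rrm2 copy rrm2_ENSDARG00000078069 had 1 UMI against 173, a ratio of 262 with a 95% counting interval of 46.4 to 10410. The gene tnfrsf18 had 1 against 84, a ratio of 127 with an interval of 22.2 to 5084. Of 27 immediate early and heat shock genes 1 rose (13 adjusted over the list alone; camera adjusted p = 3.8e-05, adjusted p = 0.755 with an estimated correlation). The gene myb differed by 0.50 ± 0.20 (adjusted p = 0.288). Without drl library 1 or 2 edgeR called 1 and 0 genes (328 at unadjusted p under 0.05 for the latter), and 375 and 310 without runx1 library 1 or 2. DESeq2 called 60 with all libraries. With ranked doublet scores, which named 331 lymphoid-like cells in place of 219, edgeR called 182 genes, 18 of the 22 among them.

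In neutrophil-like cells of the drl sort, with libraries of at least 10 cells, 3 of 3193 genes changed between 30 and 52 hpf in edgeR (355 at unadjusted p under 0.05; DESeq2 called 48). The gene C7H18H7H19orf12 rose from 2.87 ± 0.434 to 162 ± 47.7 CPM (5.69 ± 0.48, adjusted p = 0.0226). The others were cst14b.2, which fell (-5.55 ± 0.47, adjusted p = 0.0226), and si:ch73-359m17.5, both leading genes of neutrophil-like clusters.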
